A study of Chlamydomonas reinhardtii with 15 samples.

How the data were processed

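Total RNA of 15 cultures was hybridised in 1 colour (Cy3) to custom Agilent arrays designed on version 4 of the JGI transcript models, per the labels' protocols. The labels assign the arrays to control, NR, tBOOH, DBMIB and Hexenal, 3 each, and describe the replicates as independent biological ones. The array carries 15243 probes of the specific class and 1040 of the cross-hybridising class, in 1 to 10 spots each, 43803 spots in all.

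For each of the 12 treated arrays a scanner table was used, holding background-corrected processed signal intensity per spot as deposited, on a linear scale and not normalized between arrays; the software version is not given in the sources used here. The control arrays enter only through the table of the whole series, whose log2 values the authors deposited for all 15 arrays. What that table holds was worked out from its values. Its columns rank the probes exactly as the mean log2 processed signal over all spots of a probe does (Spearman correlation 1 for each of the 12 treated arrays). Every sorted column is the same within 0.01 and every median is 6.953, so the authors' values were quantile-normalized; they are not centred per probe, and a 1-colour table has no direction of ratio. No 2 columns were identical.

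Treated groups were compared with control on the deposited log2 values, in 1 limma model (lmFit and eBayes, limma 3.58.1, R 4.3.3) over the 5 groups, so that each probe has 1 estimate of spread. The 6 comparisons between treatments used log2 of the processed signal minus the array's 75th percentile, over the 4 treated groups. Spots flagged by the scanner software as non-uniform or as population outliers, 1.45% to 1.67% of spots per array, were left out there unless every spot of a probe was flagged; the remaining spots of a probe were averaged. This was done after counts with all spots had been seen, which are kept as an alternative. The deposited values average all spots. Control features, 60 in the deposited table, were kept out of the tests. No filter on dim probes and no pseudocount was used. A probe was called at a two-sided adjusted p under 0.05 over 16283 probes. A probe counted as well above background on an array when at least 0.5 of its spots were. Where a probe was not well above background on any array of a treated group, or, between treatments, on at least 1 array of the dimmer group, its change is given as at least N-fold: the brighter group's mean against the mean, per array, of the higher of the probe's own value and the lowest value among probes well above background (between treatments, judged on the spots kept). Between treatments, a bound equals the fitted fold where that lowest value lies below the probe's own values, and the fitted fold is then given. Bounds do not cover the spread between arrays, so a fit without 1 array can go below them. Changes against control with 1 or 2 of 3 treated arrays well above background are given as fitted, with that number. Flags of the control arrays were not used here. Of treated deposited values from 4 to 5, 86.6% were well above background, of those from 3 to 4, 39.6%, and of those below 3, 0.885%. The lowest value well above background is thus an extreme, and a transcript not detected may lie above it. Folds given as at least N are therefore nominal and not strict limits.

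The model was tested on simulated data before use. Only 67, 67 and 66 of 16283 probes were changed, by log2 0.5, 1 and 2. It recovered 4.48%, 53.7% and 95.5% of these in the comparison of NR with control, and 4.48%, 46.3% and 84.8% in that of NR with tBOOH. False calls among unchanged probes numbered 10 and 4 in the same order. So few changed probes make an adjusted p under 0.05 harder to reach than in the data, where 45.03% to 61.9% of probes were called against control. These recovered shares therefore do not carry over to the data. The test of neighbouring loci called 6.3% of 1000 simulated sets of 3000 independent loci at p of 0.05 or less.

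Each probe carries a JGI transcript number. These were matched to older locus tags in an NCBI RefSeq table of assembly Chlamydomonas_reinhardtii_v5.5, which is a later build than the array's, so no coordinates are given and the table served only for locus tags and their order. Of 7899 numbers below 200000, 6854 (86.8%) matched, against 16.1% when the numbers were shifted; from 200000 on, matches were at the level of shifted numbers (43.8% against 42.1%) or absent, and those probes stay unnamed. The table gave 0 gene symbols for the loci. The gene lists fixed before the data were examined need symbols or descriptions, so no list was tested, and the rule for named genes, which needs them too, named none. In its place, set when the tables were found to hold no symbols and before fold changes were computed, the text names the 2 higher and 2 lower probes with the largest change per comparison, among called probes with a locus tag whose 2 groups of arrays do not overlap, 1 probe per locus. For responses shared by all 4 treatments it takes the 2 probes in each direction whose smallest change is largest. Of 50 transcripts measured with 3 probes each, 1 to 5 had probes called in both directions, depending on the treatment. All 3 probes were called in 1 direction for 8 transcripts under NR, 10 under tBOOH, 11 under DBMIB and 6 under Hexenal. No probe was called for 17, 13, 15 and 8 in the same order. In the remaining transcripts the probes disagreed on the call, so a call of 1 probe need not hold for its transcript.

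The effect of shared controls was examined with 100 simulations of unchanged groups, and no count or p-value was adjusted for it. Alternatives covered the scaling, the background correction (normexp, offset 50), a filter on dim probes, the moderation, array weights, the samples in the fit, the replicate number as a block and leaving out each replicate. After the data were seen, spike-in centring, the place of an array on its slide, that centring without each control, leaving out tBOOH replicate 1 and DBMIB replicate 2, leaving out cross-hybridising probes, normexp without strongly negative spots and keeping outlier spots were added. Same-numbered arrays were checked for shared deviations from their group means: all 3 same-numbered pairs correlated above 0.1 in 4 of 10 pairs of groups (control and NR, tBOOH and DBMIB, tBOOH and Hexenal, DBMIB and Hexenal), where the pairing comes from these correlations and not from the labels. Slide identity and scan date are not given in the sources used here, so no slide block was fitted. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.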

Results

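Transcript levels were measured in the green alga Chlamydomonas reinhardtii, strain 4A+ (a wild type in the 137c background), after 2 h of exposure to 1 of 4 chemicals or to none. The chemicals were neutral red (NR, 3 µM), a dye that forms singlet oxygen in light; tert-butylhydroperoxide (tBOOH, 100 µM), an organic hydroperoxide; DBMIB (2 µM), a quinone that blocks photosynthetic electron transport at the cytochrome b6f complex; and 2(E)-hexenal (Hexenal, 0.3 mM), a reactive unsaturated aldehyde. Each of the 5 groups had 3 biological replicates, so 15 one-colour arrays were compared over 16283 probes. A probe stands for 1 transcript model, and 6942 probes (42.6%) could be tied to 1 of 6854 locus tags of the v5.5 annotation. Loci are named by these tags, because the tables used here pair none of them with a gene symbol. On the 12 treated arrays, between 72.7% (DBMIB replicate 2) and 89.8% (NR replicate 2) of probes were well above background, and no spot was saturated. The number of arrays limits the precision of every value below.

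Arrays of 1 group resembled each other more than arrays of different groups. Pearson correlations across probes, which are not independent replicates, lay between 0.983 and 0.995 within groups. Control and treated arrays correlated at 0.866 to 0.954, and arrays of different treatments at 0.896 to 0.959. NR arrays were the closest to control, with a median correlation of 0.940, against 0.887 for tBOOH, 0.882 for DBMIB and 0.886 for Hexenal. The first 2 principal components carried 42.9% and 24.7% of the variance.

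**Figure D1:**
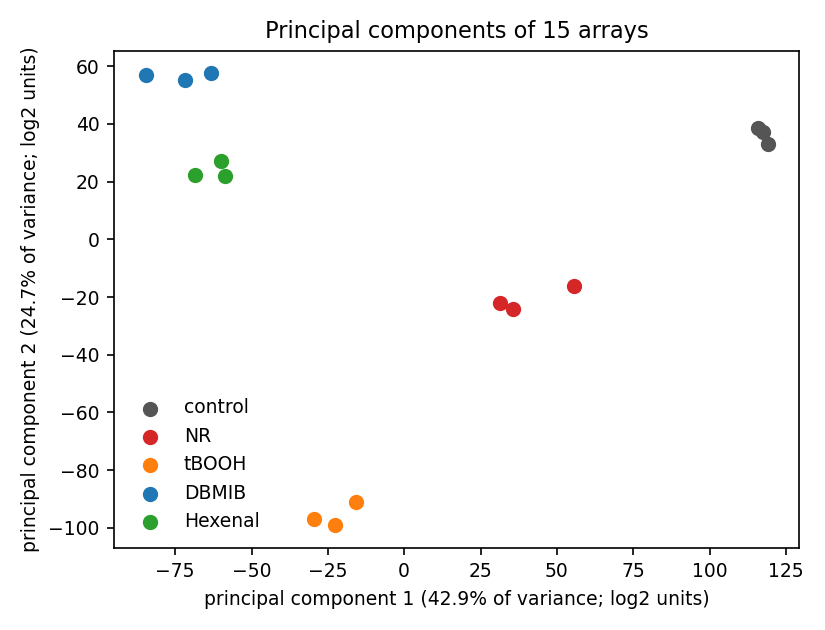
Scores of the 15 arrays on the first 2 principal components of the quantile-normalized log2 values (axes in log2 units, with the share of variance, 42.9% and 24.7%), 1 point per array, coloured by group. Each group of 3 arrays lies apart from the others, with NR nearest to control and tBOOH at the lower end of the second component.

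The question asked of each treatment against control was which transcripts change under oxidative or electrophilic stress. Values here are the deposited quantile-normalized log2 signals, given as mean ± SD over 3 arrays; changes are log2 differences with the standard error of limma's moderated test, and adjusted p-values are limma's, by the Benjamini-Hochberg method.

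NR raised CHLRE_16g688550v5 from 11.85 ± 0.06 in control to 18.21 ± 0.03, an 81.9-fold rise (log2 change 6.36, SE 0.166, adjusted p = 1.19e-11). CHLRE_06g263550v5 rose 60.5-fold, from 6.58 ± 0.52 to 12.50 ± 0.85 (adjusted p = 1.64e-08). CHLRE_09g390615v5 fell by 6.40 on the log2 scale, from 11 ± 0.44 to 4.60 ± 0.16 (SE 0.430, adjusted p = 5.25e-08). CHLRE_12g505250v5 fell from 7.49 ± 0.48 to a signal not well above background on any of the 3 NR arrays, nominally at least 36.7-fold lower (adjusted p = 3.33e-08). Across all probes, 3860 were called higher and 3472 lower, 7332 in all (45.03%), and 2029 higher and 1990 lower probes differed by at least 2-fold. At least 8-fold changes were found for 123 higher and 188 lower probes. Centred on 6 spike-in features instead, a scaling chosen after the data were seen, 5478 probes were called, and 41.4% of these were higher, against 52.6% on the deposited scale. That shift rests on control replicate 1, without which 55.2% of 5287 calls were higher with the same centring, against 38.2% of 4544 without control replicate 2 and 33.3% of 4923 without control replicate 3.

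Under tBOOH the 2 loci with the largest rises were CHLRE_13g586950v5 and CHLRE_13g586450v5. The first rose 214-fold, from 6.38 ± 0.48 to 14.12 ± 0.31 (log2 change 7.74, SE 0.224, adjusted p = 3.42e-11), but its probe is of the array's cross-hybridising class and may read related transcripts. CHLRE_13g586450v5 has a specific probe and rose 123-fold, from 10.70 ± 0.35 to 17.64 ± 0.26 (adjusted p = 4.87e-11). Both also rose under the other treatments, by 5.41 to 6.40 on the log2 scale under NR and Hexenal and by 3.95 and 3.19 under DBMIB. CHLRE_03g199535v5, at 15.36 ± 0.02 in control, fell by 9.35 on the log2 scale to 6.01 ± 0.43 (SE 0.631, adjusted p = 1.45e-08). CHLRE_03g162800v5 fell by 8.85, to 4.08 ± 0.01, with 2 of 3 tBOOH arrays well above background; its control level was 12.93 ± 2.43, so that fold is loosely set (SE 1.29, adjusted p = 2.93e-05). Its log2 change was -7.51 without control replicate 1 and -9.89 without control replicate 3. In total 9784 probes (60.1%) were called, 5193 higher and 4591 lower, and 3185 and 3225 of them differed by at least 2-fold. With spike-in centring the calls numbered 8089, of which 42.7% were higher, against 53.1% on the deposited scale; without control replicate 1 the share with that centring was 50.6%.

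DBMIB gave the largest rise among called loci with a tag in the 4 comparisons with control. CHLRE_07g318800v5 went from 4.26 ± 1.07 in control to 16.09 ± 0.26 (log2 change 11.83, SE 0.687, adjusted p = 3.73e-09). CHLRE_07g318850v5 went from 4.33 ± 0.65 to 15.14 ± 0.09 (log2 change 10.81, SE 0.859, adjusted p = 6.64e-08). Of the 6 control values of both loci, 3 lay between 3 and 4, a range in which 39.6% of treated values were well above background, so these rises rest on control signals near background. Without control replicate 2 the rise of CHLRE_07g318800v5 was 12.43. Under Hexenal they rose by 7.76 and 4.76, and under NR by 3.97 and 3.29. Under tBOOH the changes were 0.33 (adjusted p = 0.704) and 0.51 (adjusted p = 0.637), which did not pass the threshold. CHLRE_12g546550v5 fell by 6.59 under DBMIB, from 11.30 ± 0.58 to 4.71 ± 1.15 (SE 0.599, adjusted p = 2.41e-07), with 2 of 3 DBMIB arrays well above background; without DBMIB replicate 2 the log2 change was -5.93. CHLRE_03g162800v5 fell by 8.13 (SE 1.29, adjusted p = 6.07e-05), again with 2 of 3 arrays well above background. That change was -6.80 without control replicate 1, -9.17 without control replicate 3, -7.52 without DBMIB replicate 1 and -9.30 without DBMIB replicate 3. The calls numbered 10084 (61.9%), of which 5134 were higher and 4950 lower, with 3193 and 3586 at 2-fold or more. Spike-in centring turned this balance, since 24.2% of the 9618 calls were then higher, against 50.9% on the deposited scale. Of the probes called at 2-fold or more, 24.3% were higher with that centring, against 47.1%. Without control replicate 1 the share among all calls was 30.9%.

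Hexenal raised CHLRE_10g428950v5 932-fold, from 7.64 ± 0.09 to 17.50 ± 0.09 (log2 change 9.86, SE 0.272, adjusted p = 2.57e-12). The same locus rose by 6.74 under DBMIB, 3.96 under tBOOH and 2.83 under NR. CHLRE_12g556228v5 rose 543-fold under Hexenal, from 4.52 ± 0.28 to 13.60 ± 0.12 (adjusted p = 7.15e-14), and by nearly as much under DBMIB (13.57 ± 0.11), whereas NR and tBOOH brought it to 5.49 ± 0.13 and 5.88 ± 0.16. CHLRE_03g199535v5 fell by 8.41, to 6.95 ± 1.10 (SE 0.631, adjusted p = 3.80e-08); without Hexenal replicate 3 the log2 change was -9.03. CHLRE_03g162800v5 fell by 8.51, to 4.42 ± 0.38 (adjusted p = 4.67e-05), with 2 of 3 Hexenal arrays well above background, and its change was -7.18 without control replicate 1 and -9.55 without control replicate 3. Among all probes 5142 were called higher and 4187 lower, 9329 in all (57.3%), and 2950 and 2987 differed by at least 2-fold. With spike-in centring 36.7% of 7471 calls were higher, against 55.1% on the deposited scale, and of those at 2-fold or more 35.2% were higher, against 49.7%. Without control replicate 1 the share among all calls was 46.0%.

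**Figure D2:**
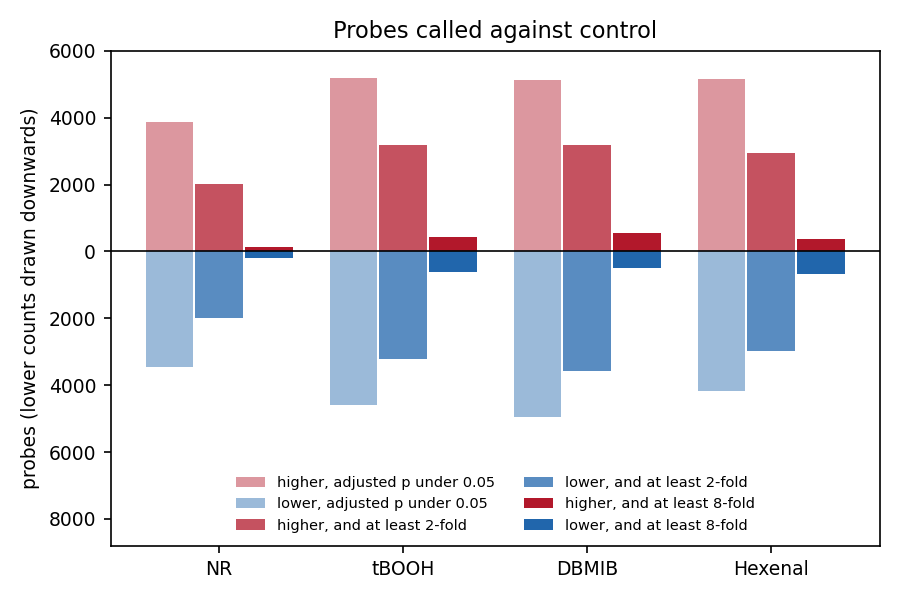
Number of probes (vertical axis) with limma adjusted p under 0.05 in each treatment against control, drawn upwards for higher and downwards for lower probes, for all calls, calls of at least 2-fold and calls of at least 8-fold, n = 3 arrays per group. In this model NR has the fewest calls in total (7332) and DBMIB the most (10084). DBMIB did not have the most with array weights, nor with only the treated group and the controls in the fit, nor without tBOOH replicate 1 and DBMIB replicate 2.

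**Figure D3:**
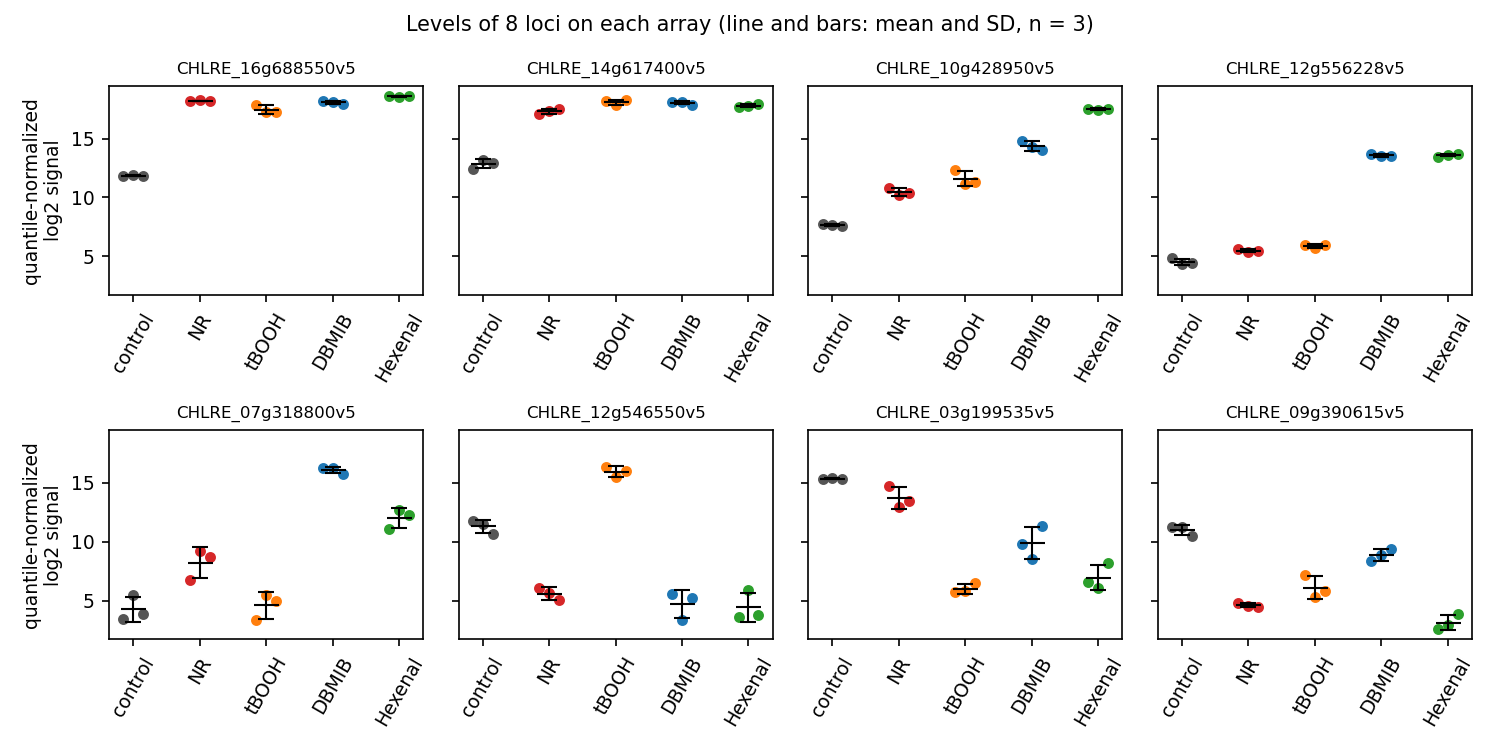
Quantile-normalized log2 signal (vertical axis) of 8 named loci on each array, 1 point per array, with the mean (line) and SD (bars) of the 3 arrays of each group. CHLRE_16g688550v5 and CHLRE_14g617400v5 are above control in all 4 treatments, and CHLRE_12g546550v5 is above control under tBOOH (15.96 ± 0.44) and below it under the other treatments.

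The 4 treatments shared a large part of these changes. CHLRE_16g688550v5 rose 81.9-fold under NR, 49.2-fold under tBOOH, 74.7-fold under DBMIB and 108-fold under Hexenal. CHLRE_14g617400v5, at 12.87 ± 0.38 in control, rose 21.8-fold, 37.3-fold, 35.9-fold and 30.3-fold in the same order, with adjusted p between 8.82e-11 and 1.72e-09. CHLRE_03g162800v5 fell by 5.35 under NR (adjusted p = 0.00354); its log2 change was -8.85 under tBOOH, -8.13 under DBMIB and -8.51 under Hexenal. Single arrays moved the NR change, to -4.02 without control replicate 1, -6.39 without control replicate 3, -6.87 without NR replicate 1 and -4.18 without NR replicate 3. By replicate number, however, the 2 groups ran in parallel, at 15.59, 12.35 and 10.84 in control and 10.61, 6.88 and 5.24 under NR. Leaving out an array of 1 group only breaks this parallel, which is read from the data and not from the labels. Leaving out control replicate 1 or 3 moved the others as given above. CHLRE_04g222600v5, at 6.04 ± 1.39 in control, was not well above background on any treated array. It was nominally at least 13.4-fold lower under NR, 9.52-fold under tBOOH, 7.45-fold under DBMIB and 7.71-fold under Hexenal (adjusted p between 1.07e-06 and 3.31e-06). These bounds rest in part on control replicate 2, at 7.589 against 4.928 and 5.589 on the other control arrays; without it they were 7.81-fold, 5.56-fold, 4.35-fold and 4.50-fold in the same order. In all, 1805 probes were called higher and 1853 lower in every treatment, 22.5% of those tested. Lists drawn independently would share 122.6 and 76.5 probes, and 100 simulations of unchanged groups against the same controls gave 0, a count that says nothing about lists of this length because unchanged groups give hardly any calls. The median log2 change of the shared higher probes was 1.27 under NR, 1.64 under tBOOH, 1.63 under DBMIB and 1.55 under Hexenal, and that of the shared lower probes was -1.29, -2.02, -2.004 and -2.16. Because 3 controls are too few to give each treatment controls of its own, part of the excess may come from the shared controls. With spike-in centring 2733 probes were shared, of which 28.0% were higher, against 49.3% of 3658 on the deposited scale; without control replicate 1 the share was 41.6% of 2538.

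DBMIB and Hexenal had the most similar fold changes and NR and DBMIB the least. Pearson's r of log2 fold changes across probes was 0.81 for DBMIB and Hexenal, with a covariance of 1.94. It was 0.70 for NR and tBOOH (covariance 1.12), 0.70 for NR and Hexenal (1.13), 0.69 for tBOOH and Hexenal (1.60), 0.64 for tBOOH and DBMIB (1.52) and 0.56 for NR and DBMIB (0.92). Unchanged groups against the same controls gave r of 0.50 and a covariance of 0.0346 in simulation. DBMIB and Hexenal shared 3739 higher and 3414 lower probes, where independent lists would share 1621 and 1273. That benchmark takes no account of the shared controls.

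Some responses set 1 treatment apart from control and from each of the other treatments, by at least 2-fold and with a call in every comparison. By this measure tBOOH had 727 higher and 391 lower probes, DBMIB 638 and 444, Hexenal 227 and 383, and NR 108 and 78. Calls against control used the deposited values and calls between treatments the scanner signals, and no recount with other scalings was made. Of calls between Hexenal and NR, tBOOH and DBMIB, 62.4%, 57.6% and 58.7% were lower under Hexenal on the scanner scale. On the deposited scale these shares were 50.5%, 50.4% and 45.7%. The splits into higher and lower probes may therefore depend on the scaling.

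Differences between treatments were tested on the scanner signals of the 12 treated arrays, each centred on its 75th percentile, in which a log2 value of 0 is that percentile. Among called probes with a locus tag, NR and tBOOH differed most in CHLRE_12g546550v5, which was 1405-fold higher under tBOOH (6.73 ± 0.29) than under NR (-3.73 ± 0.42, adjusted p = 2.72e-07). CHLRE_12g546500v5 was nominally at least 122.5-fold higher under tBOOH, since it was not well above background on any NR array (adjusted p = 5.09e-09). Higher under NR were CHLRE_03g199535v5, 215-fold, and CHLRE_03g158000v5, 180-fold (adjusted p = 2.86e-06 and 6.64e-08). Against control both fell in both treatments, with log2 changes of -1.65 and -1.11 under NR and of -9.35 and -8.475 under tBOOH. The calls numbered 7725, of which 4048 were higher under NR and 3677 lower.

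Between NR and DBMIB, CHLRE_16g667950v5 and CHLRE_13g577300v5 were nominally at least 570-fold and at least 332-fold higher under DBMIB (adjusted p = 8.63e-10 and 2.29e-07). Neither was well above background on any NR array. CHLRE_10g429050v5 was 40.6-fold and CHLRE_09g398700v5 35.8-fold higher under NR (adjusted p = 5.49e-08 and 2.23e-08). For the first of these, 2 of 3 DBMIB arrays were well above background. Of 9228 calls, 4625 were higher and 4603 lower under NR.

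Between NR and Hexenal, CHLRE_16g667950v5 was nominally at least 293-fold higher under Hexenal and CHLRE_12g556228v5 315-fold higher (adjusted p = 3.49e-09 and 6.09e-12). Higher under NR were CHLRE_03g199535v5, 123-fold, and CHLRE_16g663900v5, 115-fold, the latter with 1 of 3 Hexenal arrays well above background (adjusted p = 5.33e-06 and 4.43e-05). Without Hexenal replicate 3 these were 195-fold and 197-fold. Against control their log2 changes were -1.65 and -1.27 under NR, the latter not called, and -8.41 and -7.73 under Hexenal. Of 7163 calls, 4471 were higher and 2692 lower under NR.

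Among called probes with a locus tag, CHLRE_12g546550v5 also led those higher under tBOOH than under DBMIB, nominally at least 2307-fold (2 of 3 DBMIB arrays well above background, adjusted p = 2.82e-08). CHLRE_09g393150v5 followed, 211-fold (adjusted p = 1.10e-09). Against control its log2 change was 2.40 under tBOOH and -5.15 under DBMIB. In the other direction, CHLRE_07g318800v5 was nominally at least 3872-fold and CHLRE_07g318850v5 1588-fold higher under DBMIB (adjusted p = 3.27e-08 and 1.06e-06). Each had 2 of 3 tBOOH arrays well above background. Single arrays moved the fitted folds, from 2811-fold to 1598-fold for CHLRE_12g546550v5 without DBMIB replicate 2 and from 3943-fold to 2369-fold for CHLRE_07g318800v5 without tBOOH replicate 1. Both lower folds lie below the bounds given, which do not cover the spread between arrays. This comparison gave 8150 calls, 4069 higher and 4081 lower under tBOOH.

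Against Hexenal, tBOOH gave 4020-fold more signal for CHLRE_12g546550v5 (1 of 3 Hexenal arrays well above background, adjusted p = 2.52e-08) and 433-fold more for CHLRE_12g546600v5 (adjusted p = 2.77e-08). CHLRE_12g556228v5 was 257-fold and CHLRE_07g318800v5 nominally at least 206-fold higher under Hexenal, the latter with 2 of 3 tBOOH arrays well above background (adjusted p = 1.03e-11 and 1.53e-06). The fitted fold of CHLRE_12g546550v5 was 6582 without Hexenal replicate 2. That of CHLRE_07g318800v5 was 126 without tBOOH replicate 1, below its bound, against 209 with it. There were 7505 calls, 4321 higher and 3184 lower under tBOOH.

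DBMIB and Hexenal, the closest pair, still differed 209-fold in CHLRE_11g467644v5 and 133-fold in CHLRE_03g146207v5, both higher under DBMIB (adjusted p = 8.81e-07 and 1.36e-08). CHLRE_10g434350v5 was 24.3-fold and CHLRE_10g434650v5 22.4-fold higher under Hexenal (adjusted p = 1.63e-05 and 2.79e-06). Against control the first had log2 changes of 3.78 under Hexenal and -0.71 under DBMIB, the latter not called. The second had 0.59 under Hexenal, not called, and -3.81 under DBMIB. Of 6836 calls, 4010 were higher and 2826 lower under DBMIB.

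The share of calls higher in the first-named treatment moved with the scaling. On the 75th percentile scale it was 52.4% for NR against tBOOH, 50.1% for NR against DBMIB, 62.4% for NR against Hexenal, 49.9% for tBOOH against DBMIB, 57.6% for tBOOH against Hexenal and 58.7% for DBMIB against Hexenal. With spike-in centring the shares were 66.2%, 80.8%, 80.1%, 72.3%, 64.3% and 36.2% in the same order. On the deposited quantile-normalized scale they were 48.9%, 51.3%, 50.5%, 53.5%, 50.4% and 45.7%. Directions of the named loci held under each of these scalings, but these loci were picked for their large changes, so this says little about other calls.

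The array's spike-in features give the background for these splits. The mean log2 signal of the 6 E1A features, after the deposited normalization, was 11.82 ± 0.33 in control, 11.96 ± 0.09 under NR, 12.03 ± 0.32 under tBOOH, 12.45 ± 0.21 under DBMIB and 12.15 ± 0.04 under Hexenal (SD, n = 3). Relative to these features the median log2 change of all probes was -0.13 under NR, -0.11 under tBOOH, -0.57 under DBMIB and -0.20 under Hexenal, where on the deposited scale it was 0.01, 0.10, 0.06 and 0.13. Control replicate 1, at 11.45 against 11.94 and 12.08 on the other control arrays, carries much of this: without it the medians relative to the spike-in features were 0.05, 0.06, -0.40 and -0.02. The differences from control in E1A signal of DBMIB, 0.63, and of Hexenal, 0.32, each had p = 0.1 in a two-sided exact permutation test, the smallest p that 3 arrays against 3 can give; for tBOOH (0.21) p was 0.5 and for NR (0.14) 0.9 in the same exact test. Without control replicate 1 the differences were 0.44 for DBMIB, 0.14 for Hexenal, 0.02 for tBOOH and -0.05 for NR.

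**Figure D4:**
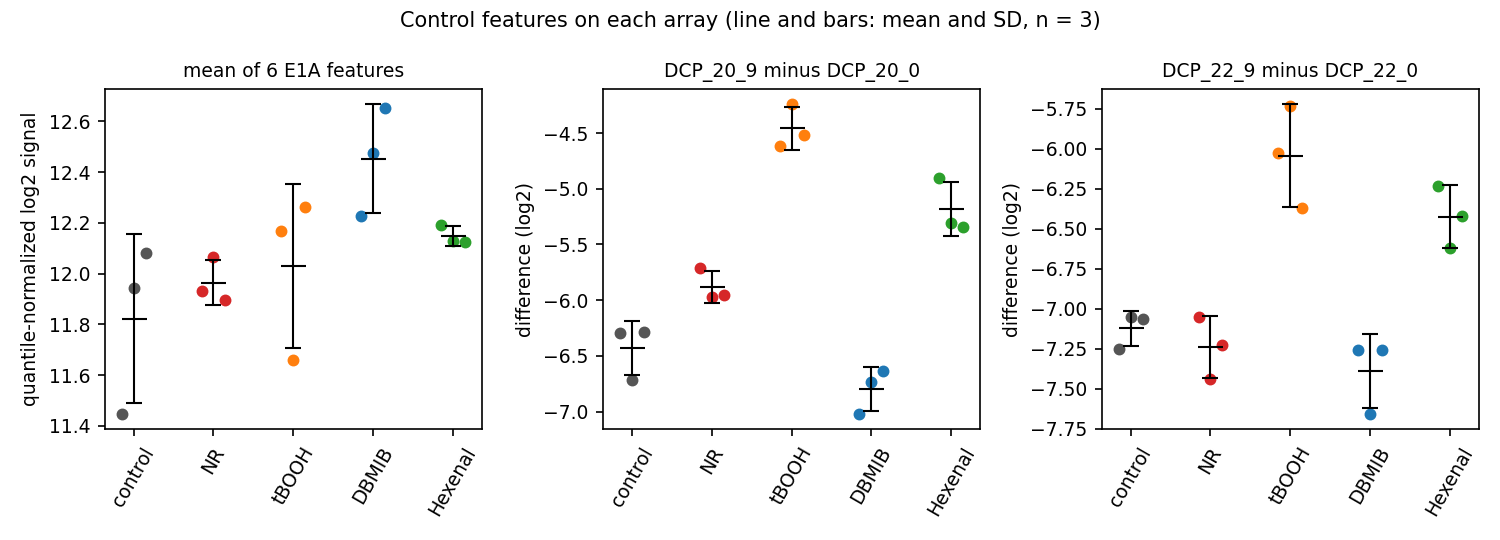
Quantile-normalized log2 signal of control features on each array, 1 point per array, with the mean (line) and SD (bars) of the 3 arrays of each group: the mean of 6 E1A spike-in features (left), and the signal of DCP_20_9 (middle) and DCP_22_9 (right) relative to DCP_20_0 and DCP_22_0 (log2 difference). The DBMIB mean in the left panel is 12.45 against 11.82 in control, and the tBOOH and Hexenal arrays lie above the control arrays in both other panels.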

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

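The tests of the shared controls, of spike-in scatter at every level, of the second deletion series and of the DBMIB signal were chosen after the results they bear on were seen; the others were set before.

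Some probes moved in opposite directions under 2 treatments, with both calls against control, at least 2-fold apart and a call between the treatments. There were 861 for tBOOH and DBMIB, 807 for NR and DBMIB, 703 for tBOOH and Hexenal, 393 for NR and tBOOH, 367 for NR and Hexenal and 352 for DBMIB and Hexenal. By the calls against control alone, 467 probes were higher under tBOOH and lower under DBMIB, and 413 the other way. Independent lists would give 1579 and 1448. In every pair of treatments opposite calls were fewer than independent lists would give, a benchmark that takes no account of the shared controls. CHLRE_12g546550v5 is among the probes that moved in opposite directions, with log2 changes of 4.66 under tBOOH, -5.71 under NR, -6.59 under DBMIB (2 of 3 arrays well above background) and -6.88 under Hexenal (1 of 3 arrays).

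Control features outside the comparisons were scanned for groups in which all 3 treated arrays lay above all 3 controls by a mean of over 1 log2 unit. Of 60 features and 4 treatments, 7 combinations met this. DCP_20_9 was higher by 2.24 under tBOOH and by 1.74 under Hexenal, DCP_22_9 by 1.27 and 1.03, and DCP_20_7 by 1.045 under tBOOH. The feature eQC-39 was higher by 1.71 under tBOOH, at a dim level (3.47 ± 0.39 against 1.76 ± 0.17). E1A_r60_a135 was higher by 1.05 under DBMIB (8.43 ± 0.24 against 7.38 ± 0.36).

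The sharing of fold changes by the 4 treatments is the first pattern weighed. Shared control arrays alone would give the simulated covariance, and the lowest observed one is 26.7 times that; leaving out 1 control at a time left at least 3130 probes called in all 4 treatments, against 3658 with every control, which argues against 1 deviating control. A shift of probes by hybridising the controls apart would scatter spike-in features too. Their differences from control had an SD of at most 0.213 times that of algal probes (20 features and 13605 probes at levels 4 to 17, not matched more closely). Over all 28 features with DCP_20_9 it was at most 0.320 times. Both values argue against such a shift as the whole cause. Of resampled ratios over the 28, 95% lay between 0.149 and 0.457 under tBOOH and between 0.182 and 0.360 under Hexenal. Resampling took the features as independent, and such a shift as a part of the cause is not excluded. No day or batch label of any control array was given (0 labels), so growth, extraction or labelling of the controls on another day cannot be told apart from the absence of a chemical. A general stress response of the cells may also underlie the pattern and was not tested apart from that.

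The second pattern is the rise of DCP features, taken from their names and falling signals for Agilent's deletion series for hybridisation stringency. It is not limited to 1 series, since relative to its 0-end feature the 7-end feature of the 22 series rose by 0.614 under tBOOH and that of the 20 series by 0.78 (exact permutation p = 0.1 each, the smallest possible with n = 3). If looser hybridisation were the cause, cross-hybridising algal probes could be raised on the same arrays: against specific probes of like level they were higher by 0.14 under tBOOH and by 0.105 under Hexenal, between the bounds set in advance, and by 0.24 under DBMIB, whose 9-end features were not above control relative to the 0-end. Under NR the cross-hybridising probes were higher by 0.082. Relative to its 0-end feature DCP_20_9 was higher under NR by 0.55, with all 3 arrays above all controls. DCP_22_9 (-0.12), DCP_20_7 (-0.38) and DCP_22_7 (-0.16) were lower there. Looser hybridisation and another origin therefore cannot be told apart, and no biological explanation was tested.

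The third pattern is the higher spike-in signal of DBMIB arrays after normalization. Before it, E1A signal was 12.14 ± 0.24 (log2) on DBMIB arrays and 12.08 ± 0.12 under NR, whereas the algal 75th percentile was lower on DBMIB arrays; the gap between DBMIB and the 9 other treated arrays was -0.41 for algal probes and 0.06 for spike-in features. The difference of these gaps, -0.46, restates the pattern, because a feature's level after quantile normalization is set by its place among the algal signals, so it weighs no explanation. Less algal RNA per array, a lower messenger content of the cells and other origins of the shift were not told apart.

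Other splits of the 6 arrays of each comparison into 3 and 3 were refitted. With 10 splits per comparison the share of splits cannot go under 0.1, and in each comparison 1 split, the real one, reached the real count. The real and the highest other counts were 7332 and 0 for NR against control, 9784 and 0 for tBOOH, 10084 and 0 for DBMIB and 9329 and 1 for Hexenal. Between treatments they were 7725 and 0 (NR, tBOOH), 9228 and 0 (NR, DBMIB), 7163 and 0 (NR, Hexenal), 8150 and 1 (tBOOH, DBMIB), 7505 and 0 (tBOOH, Hexenal) and 6836 and 1 (DBMIB, Hexenal). No other split gave over 1 call, whether or not it parted the same-numbered arrays. Every other split mixes the real groups, so differences between them enter the spread and leave few calls. The low counts therefore do not measure how many of the real calls are false.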

How the results depend on the processing

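Alternatives named as added were chosen after the data were seen: spike-in centring, with all controls or without each, place on the slide, without tBOOH replicate 1 and DBMIB replicate 2, without cross-hybridising probes, normexp without strongly negative spots, and outlier spots kept. Of 269 recomputed counts of calls, 261 stayed within 1.5 times the reported count. With spike-in centring and control replicate 2 left out, 4544 probes were called for NR against control and 2348 in all 4 treatments. The 6 others came from normexp correction: 1289 calls for NR against tBOOH, 2353 for NR against DBMIB, 1494 for NR against Hexenal, 2712 for tBOOH against DBMIB, 3398 for tBOOH against Hexenal and 1103 for DBMIB against Hexenal. On NR replicate 2, tBOOH replicate 2 and tBOOH replicate 3 the normexp estimate was pulled by 2, 3 and 35 spots whose local background exceeded their signal by over 50 units, which set the median corrected signal of tBOOH replicate 3 at 2179 instead of 180. Without such spots the counts were 7542, 12082, 7113, 10748, 6810 and 8012 in the same order, and the share higher in the first treatment was 29.4% for NR against DBMIB, 47.1% for NR against Hexenal, 31.6% for tBOOH against DBMIB and 70.1% for DBMIB against Hexenal. With the first normexp correction it was 60.7% for tBOOH against DBMIB and 48.6% for DBMIB against Hexenal. Like counts can hide other probes. Of the reported calls between treatments, 69.9% to 90.1% were called the same way with the place on the slide as a block, 69.1% to 84.8% with spike-in centring and 81.0% to 89.6% with normexp without such spots, where up to 269 were called the other way (NR against DBMIB). The place on the slide was not balanced over treatments: NR arrays lay at places 3, 3 and 4 and Hexenal arrays at places 2, 2 and 3. For this pair, which had the lowest share with that block (69.9%), place and treatment can be parted only in part. Of those against control, 72.2% to 80.9% were called the same way with spike-in centring. With that centring it was 69.8% to 80.4% without control replicate 1, 60.4% to 73.1% without control replicate 2 and 64.3% to 74.5% without control replicate 3. The splits with other scalings stand beside the counts in the report. Probes that set 1 treatment apart were not recounted with other scalings. The 52 named changes, recomputed 886 times in all, kept their direction and stayed called each time. Their loci were picked for the largest called changes in the same data, so this says little about other calls.

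In the pairs of groups other than those paired by their correlations, the arrays share only a number: over all groups 20 of 30 same-numbered pairs correlated above 0.1, the lowest at -0.109, although all 15 arrays were on average closest to their own number, a hint from the data and not from the design. With the replicate number as a block the calls were 7690 for NR, 10072 for tBOOH, 10375 for DBMIB and 9626 for Hexenal against control, 3873 shared by all 4, and 8220, 9613, 7692, 8608, 7885 and 7332 between treatments. The block changed the call of no named locus, but these loci were picked for their large changes. Leaving out 1 replicate at a time gave 6004 to 7096, 8999 to 9404, 9331 to 10033 and 8477 to 9003 calls against control. Where a lone fit kept 2 arrays in a group, the spread was pooled over groups. Quantile or percentile scaling of the deposited values moved almost nothing because they were already quantile-normalized, so it says nothing about stability. No slide block and no gene list alternative was run, for want of slide identity and gene symbols, and normexp used median instead of mean spot signals. Signal over background limits the folds of dim probes, given as nominal bounds or as fitted with the number of arrays well above background.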

Other observations

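The tests of neighbouring loci were set before their results were seen, after neighbours had been noticed among the named loci; the test by correlation and those without the named loci, and the loci of this part outside the naming rule, were chosen after their values were seen. Several of the largest changes lay in loci next to each other in the v5.5 annotation. CHLRE_12g546500v5, CHLRE_12g546550v5 and CHLRE_12g546600v5 follow each other, and under tBOOH they rose by 4.07, 4.66 and 2.25 on the log2 scale. Under Hexenal the first was nominally at least 4.39-fold lower, the second fell by 6.88, with 1 of 3 Hexenal arrays well above background, and the third fell by 6.07. The pair CHLRE_07g318800v5 and CHLRE_07g318850v5 rose by 11.83 and 10.81 under DBMIB. CHLRE_14g617400v5 and CHLRE_14g617450v5 rose in all 4 treatments, by 5.17 and 4.41 under DBMIB, whereas CHLRE_14g617550v5 and CHLRE_14g617600v5 had log2 changes of -4.75 and -3.32 under NR.

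Over 3089 adjacent pairs of measured loci, their fold changes were compared with 1000 shuffled orders. By the test set in advance, the median absolute difference between neighbours, 3 of the 4 treatments (tBOOH, DBMIB and Hexenal) lay below all shuffled orders (permutation p = 0.001, the smallest they can give), but NR did not (0.87 against a shuffled median of 0.90, permutation p = 0.0749). The correlation of neighbours' fold changes was small but above all shuffled orders in each treatment: 0.114 for NR (highest shuffled value 0.0552), 0.121 for tBOOH (0.0526), 0.158 for DBMIB (0.0571) and 0.108 for Hexenal (0.0528). Without cross-hybridising probes 1 treatment, tBOOH, stayed below all shuffled orders by the median difference, with permutation p = 0.007 for DBMIB, 0.003 for Hexenal and 0.147 for NR, while the correlations were 0.114, 0.124, 0.163 and 0.114 (NR, tBOOH, DBMIB, Hexenal). Without these probes and the named loci, among which the pattern had been noticed, the correlations were 0.0972, 0.121, 0.155 and 0.113 in that order, above all shuffled orders in all 4 treatments, which argues against cross-hybridising probes of tandem copies as the whole cause; by the median difference tBOOH and Hexenal lay below all shuffled orders, with permutation p = 0.005 for DBMIB and 0.154 for NR. The hypothesis that neighbouring loci share their response may hold and stays open, because duplicated genes read by probes of the specific class could give the same picture and were not tested, and a part played by cross-hybridising probes of tandem copies is not excluded.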
